A study of Mus musculus with 4 samples.

How the data were processed

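RNA from whole pancreas of Rosa26-LSL-cas9-eGFP mice was profiled by RNA sequencing in 4 libraries. In this strain a Cas9-eGFP cassette sits at the Rosa26 locus behind a loxP-flanked stop. The labels do not say how this stop was removed, so whether Cas9 was made in these animals is not known here. Per the labels' protocols, the animals received an adeno-associated virus of serotype AAV8 in the peritoneum, carrying a guide RNA against Rosa26 or against Paf1. The tissue was ground under liquid nitrogen, RNA was extracted with TRIzol, and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The labels name acinar cells as the cell type, while the extraction they describe used ground pancreas without a sorting step, so the libraries are treated here as whole tissue.

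The deposited table holds whole-number read counts per gene name, not normalized, with the columns of a featureCounts output per the file headers. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.7a, featureCounts 2.0.1 and the mouse build GRCm38.p6 (mm10), with no role or order given for them. The annotation release and the settings for strand and for reads with several positions are not given in the sources used here. Near-identical copies such as the trypsin and amylase genes can therefore have exchanged or lost reads, and overlapping or antisense genes cannot be told apart from their partners. The table has 55492 gene names. Of these, 53253 matched a single gene of GENCODE M21, which uses the same build, and 98.2% of the matched genes had the same start and end. Coordinates are those of the deposited table, and the guides were placed on GRCm38 by an exact match to the GENCODE M21 transcripts.

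The count columns name a library number and the guide but carry no replicate number, so each column was assigned to its guide group only. There were 2 libraries per group, called control libraries A and B and Paf1 guide libraries C and D in the order of their columns. These letters are names only and pair nothing. The labels call them replicates without saying that each came from its own animal, and p-values measure only the spread between these libraries. Within each group the libraries differed by more than sampling noise, with a chi-square per degree of freedom of 7.67 in the controls and 14.9 in the Paf1 guide group, over genes with a summed count of at least 20, so none was treated as a duplicate. Library totals were 9109684, 11351866, 7183121 and 9723347 counts for A, B, C and D, respectively. A count of 3, used as the floor for a gene at 0, corresponds to 0.264 to 0.418 CPM of the library total. Floors cover counting error only, since no molecular identifiers are named in the labels.

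Genes were filtered with filterByExpr, which left 13092. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, a robust fit and no covariates, and Benjamini-Hochberg adjusted p under 0.05 as the threshold with no minimum fold. The fit's biological coefficient of variation was 16.6%. Levels are given as CPM, the counts scaled by library total and TMM factor, with the SD over 2 libraries. Log2 fold changes are Paf1 guide over Rosa26 guide, with their standard errors. The fit was tested on simulated data with 200 changed genes drawn among the 13092, in the same design. It recovered 7.46% of genes changed 1.5-fold, 38.8% of those changed 2-fold and 87.9% of those changed 4-fold, and 2.2% of the genes it called were unchanged ones. Genes were drawn independently, each with the spread that the fitted trend gives at its level. Gene-specific spread and differences shared by many genes were left out, so these rates may be better than in the real libraries.

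Before the data were examined, 39 gene lists were fixed for transcription and R-loop factors, stress and signaling responses, the cell types a dissected pancreas can hold, and general classes of genes. Of these, 37 had at least 3 tested members. Neutrophil and Schwann cell lists had fewer and were not tested. Lists were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 37 lists, and again with an estimated correlation and with fry. In the simulation, the shifted list was called with the preset correlation and was missed with the estimated one. Genes were simulated independently of each other, so this cannot decide which correlation is right for the real lists. Among the lists past the threshold, estimated correlations ran from -0.09 (sex-linked) to 0.83 (heat shock). Genes are named by a rule fixed at the same time. It takes the PAF1 complex members and the Rosa26 transcript, then the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 50 counts, no overlap between groups and a named symbol, and then up to 4 members per list with the smallest p. Genes outside this rule are marked as chosen after their values were seen.

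Alternatives were DESeq2's size factors, library totals alone, upper-quartile factors, leaving out the 50 genes with the most counts or the mitochondrial genes, no filter or a filter of at least 10 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, and each library left out in turn. Further alternatives, chosen after seeing the data, were a term for an unlabelled split of the libraries, and leaving out genes on X and Y or immunoglobulin genes. A fit with the replicate number as a block was planned and not run because the columns carry no such number. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.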

Results

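Gene expression was measured in whole mouse pancreas after delivery of a guide RNA by AAV8 to animals carrying a Cas9 allele, in 2 libraries with a Paf1 guide and 2 with a Rosa26 guide as control. PAF1 is the founding subunit of the PAF1 complex, which travels with RNA polymerase II and supports transcript elongation. The Rosa26 locus is commonly used as a neutral target. The comparison asks how the transcriptome of normal pancreas differs between the guides. Libraries held 7183121 to 11351866 counts. The 50 most abundant genes took 80.2% and 81.7% of the counts in control libraries A and B, and 76.5% and 75.6% in Paf1 guide libraries C and D. The 36 digestive enzyme genes examined took 68.9% and 70.1% against 64.5% and 64.2%.

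The Paf1 guide, GAAACACTAAAGAAACGAAAG, matched chromosome 7 from 28396665 to 28396685 on the plus strand of GRCm38, in coding exon 10 of the 14 exons of Paf1-201, with CGG as the adjacent motif. The Rosa26 guide, CACATTGCATGGATTATACA, matched chromosome 6 from 113071161 to 113071180 on the plus strand, in exon 2 of 2 of the noncoding transcript Gt(ROSA)26Sor-201, with AGG as the adjacent motif. Paf1 itself (chromosome 7, 28392951 to 28399388) had 90 and 109 counts in the control libraries and 72 and 79 in the Paf1 guide libraries. Its level was 11.1 ± 0.519 CPM in controls and 8.09 ± 1.57 CPM with the Paf1 guide (SD, n = 2), a log2 fold change of -0.46 ± 0.22 (SE) that did not pass the threshold (edgeR adjusted p = 0.369). With library totals alone as scaling it was -0.11 (adjusted p = 0.774), and without library D it was -0.25 (adjusted p = 0.809). A cut that leaves the transcript in place would not be seen in these counts. Whether Cas9 cut at all was not measured, and the labels do not say how its stop was removed. The other members of the complex, Ctr9, Cdc73, Leo1, Rtf1 and Wdr61, did not pass either, with log2 fold changes of 0.07, 0.13, -0.03, 0.21 and 0.16. The Rosa26 transcript Gt(ROSA)26Sor had 8 and 17 counts against 25 and 16 (log2 fold change 0.70 ± 0.53, adjusted p = 0.634).

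Sex-linked transcripts separated the guide groups completely. Xist, the noncoding RNA that coats the inactive X chromosome in females, had 3943 and 4543 counts in the control libraries and 4 and 7 in the Paf1 guide libraries (472 ± 5.5 against 0.565 ± 0.076 CPM, SD, n = 2; log2 fold change -9.65 ± 0.17, edgeR adjusted p = 9.17e-15). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both control libraries and between 79 and 206 in the Paf1 guide libraries. Against a floor of 3 counts per library they were at least 51.4-fold, 40.8-fold, 31.2-fold and 34.4-fold higher. As a list, the 5 sex-linked genes passed (camera adjusted p = 1.34e-16; adjusted p = 0.302 with an estimated correlation and 0.333 with DESeq2's Wald test, which gave the 4 Y-linked genes no adjusted p). Each control library thus carried the transcripts of a female and each Paf1 guide library those of a male, and every difference between the guides below is also a difference between these sexes.

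**Figure D1:**
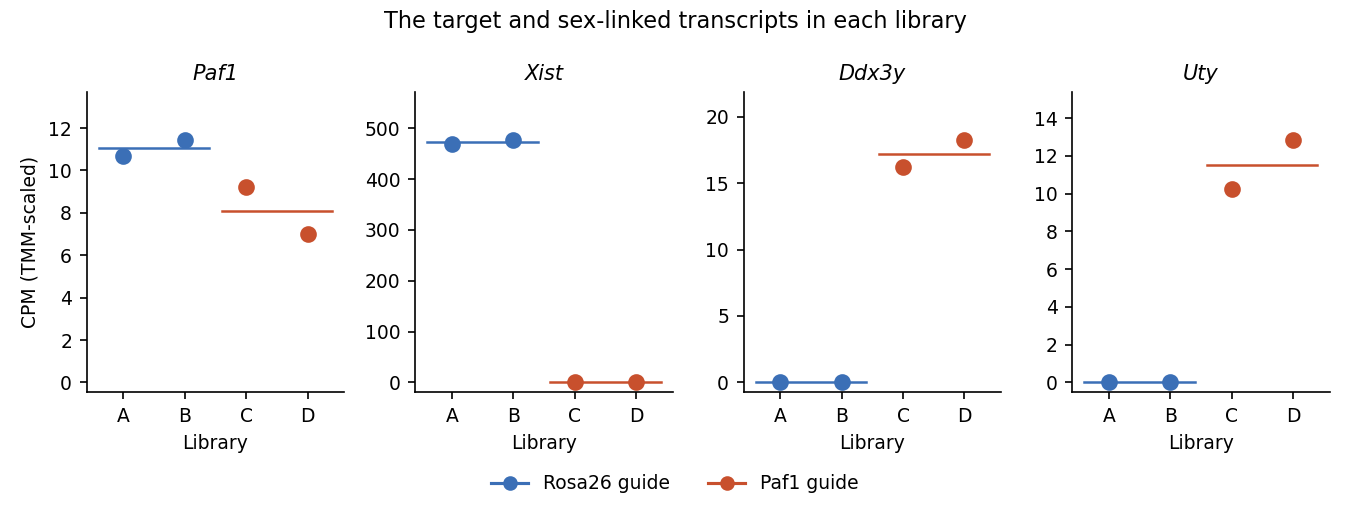
CPM of Paf1, Xist, Ddx3y and Uty (y axis, TMM-scaled, one scale per panel) in control libraries A and B and Paf1 guide libraries C and D, with points for libraries and lines for group means. Mean Paf1 is 11.1 CPM in controls and 8.09 CPM with the Paf1 guide, while Xist is near 0 in both Paf1 guide libraries and Ddx3y and Uty are at 0 in both controls.

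Across the genome, 289 of 13092 tested genes differed between the groups (edgeR, adjusted p under 0.05), 142 higher and 147 lower with the Paf1 guide. The changes included 72 rises and 32 falls of at least 2-fold. The X and Y chromosomes carried 5 changed genes each, and the other 279 were autosomal, 135 higher and 144 lower. Among tested genes, 5792 had no overlap between the groups, where chance gives 1 in 3. Genes are not independent of each other, so this count does not test a difference between the guides. With library totals alone the whole distribution shifted by 0.354 (median log2 fold change) and 1600 genes passed, 1560 of them higher. Without library A, B, C or D the count was 114, 71, 121 or 129, with 58, 50, 62 or 96 higher.

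Apart from the Y-linked genes, the largest named rise was that of Kcnj15, an inwardly rectifying potassium channel (chromosome 16, 95257558 to 95300260), from 0.807 ± 0.637 to 22.7 ± 0.239 CPM (SD, n = 2; 26.9-fold, adjusted p = 8.35e-07). Etv5, an ETS transcription factor induced by growth factor signaling (chromosome 16, 22381309 to 22439719), rose from 1.8 ± 0.474 to 19.4 ± 1.09 CPM (10.8-fold, adjusted p = 1.36e-06). Tdh, Tspan1, the vitamin D binding protein gene Gc and Tmc5 rose with log2 fold changes of 2.80, 2.43, 2.27 and 2.11. Junb, the matricellular protein gene Thbs1 and the mitochondrial carrier gene Ucp2 rose with 1.98, 1.88 and 1.79. After Xist, the largest named falls were those of Smtnl2, from 10.1 ± 0.449 to 1.82 ± 0.0473 CPM (log2 fold change -2.45 ± 0.28, adjusted p = 0.000191), and Cdhr2, an intermicrovillar protocadherin, from 14.0 ± 3.88 to 2.99 ± 1.52 CPM (-2.17 ± 0.32, adjusted p = 0.00339). Sdr9c7, Kcnh1, Aqp8 and Selenom fell by 1.47, 1.30, 1.26 and 1.21 on the log2 scale. Cald1, Nphs1, Ppp1r1b, Itih4 and Hamp2 fell by 1.18, 1.17, 1.16, 1.16 and 1.15. Kcnh1, Aqp8 and Ppp1r1b kept their direction but no longer passed with library totals alone. With a library left out directions were also kept, but Gc did not pass without A, Cdhr2, Sdr9c7 and Cald1 without B, Tspan1 without C, Itih4 without A or B, Hamp2 without B or D, Tmc5 without B or C, Junb without A, B or C, Kcnh1 and Selenom without B, C or D, and Aqp8 and Ppp1r1b whichever library was left out. Kcnh1, Aqp8, Selenom, Ppp1r1b and Junb did not pass with limma-voom (adjusted p = 0.130, 0.126, 0.0633, 0.0567 and 0.0502). DESeq2's Wald test gave no adjusted p for these genes or for Tdh, Tspan1, Gc, Tmc5, Smtnl2 and Cdhr2.

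Digestive enzyme genes were lower than other genes with the Paf1 guide. Of the 36 examined, all tested, 14 fell, 3 rose and 19 did not pass, with a median log2 fold change of -0.43 (camera adjusted p = 0.000463; adjusted p = 0.943 with an estimated correlation). With library totals alone the median was -0.08, against 0.354 in all genes, and 9 fell and 5 rose. Adjusted over the list alone, 24 fell and 4 rose. Pnliprp1, a pancreatic lipase-related gene, went from 18767 ± 1053 to 9575 ± 683 CPM (SD, n = 2; log2 fold change -0.97 ± 0.11, edgeR adjusted p = 0.000124), and the amylase gene Amy2a2 from 22090 ± 1489 to 11550 ± 63.2 CPM (-0.94 ± 0.10). Of 12 trypsin genes, 7 rose past the threshold and 1, Try10, fell, by 0.86 on the log2 scale. Prss1 rose from 18.5 ± 0.573 to 47.8 ± 8.2 CPM (log2 fold change 1.38 ± 0.14), and Prss3, Try5, Gm10334 and Gm5771, named after their values were seen, rose by 1.24, 0.59, 1.26 and 2.45. The other 2 that rose, Gm2663 and 1810009J06Rik, chosen in the same way, had 3 to 8 counts in each control library and 19 to 67 in each Paf1 guide library. Trypsin and amylase copies are nearly identical in sequence, and their separate values are uncertain. Summed over 8 amylase genes the log2 ratio was -0.68 with no overlap between the groups, and summed over 12 trypsin genes it was -0.05 with overlap. The enzyme list did not pass without library B. Its median was -0.53, -0.28, -0.42 or -0.35 without library A, B, C or D. Without library A, B, C or D, 15, 5, 9 or 6 members fell. With the 50 most abundant genes left out, 6 enzymes remained tested and camera's direction turned (adjusted p = 0.783).

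**Figure D2:**
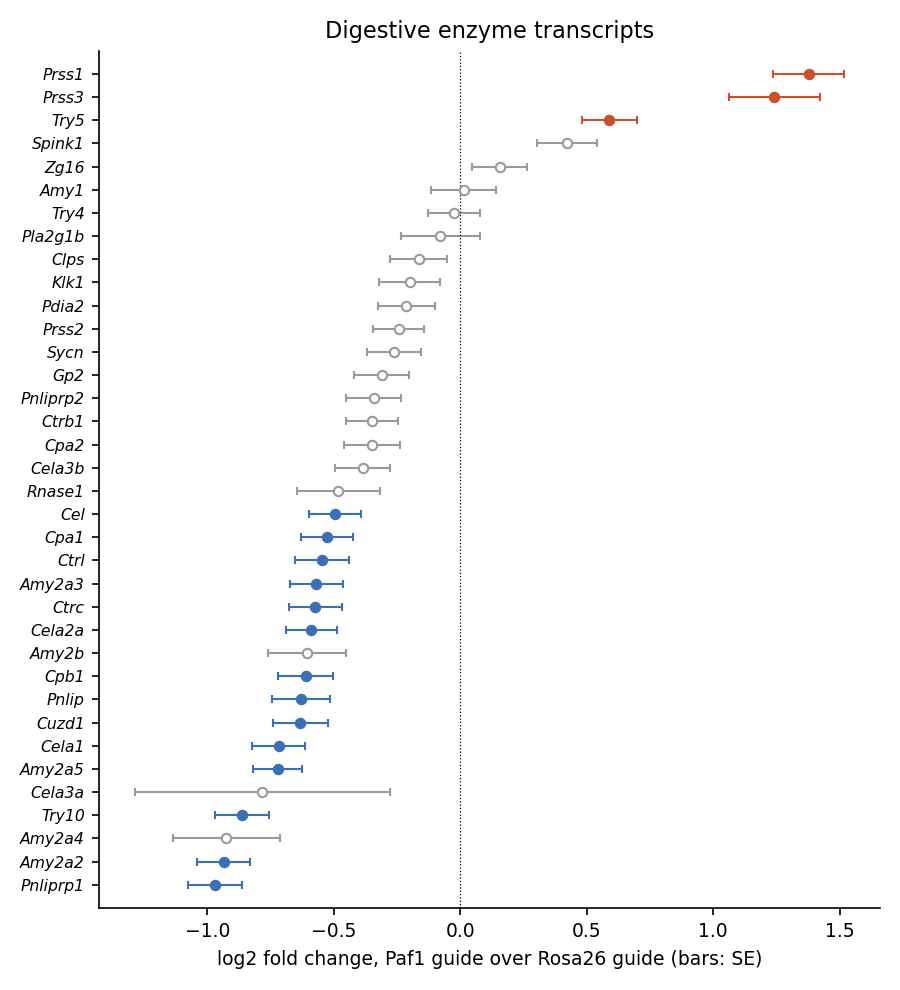
Log2 fold change (x axis, Paf1 guide over Rosa26 guide, bars SE) of 36 digestive enzyme genes, with filled points past adjusted p 0.05, blue lower and red higher, and open points for the rest. The 14 genes that fell lie between -0.97 and -0.50, and the 3 that rose, Prss1, Prss3 and Try5, between 0.59 and 1.38.

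Genes that regulate or serve acinar secretion leaned the same way. Of 25 tested, 5 fell, 1 rose and 19 did not pass, with a median log2 fold change of -0.17 (camera adjusted p = 0.0135; adjusted p = 0.859 with an estimated correlation). Without library A, B, C or D the median was -0.20, -0.11, -0.28 or -0.11. The median turned to 0.19, still below the shift of 0.354 in all genes, with library totals alone (adjusted p = 0.259), when 3 members rose and none fell. The acinar water channel Aqp12 went from 176 ± 11.5 to 111 ± 2.72 CPM (SD, n = 2; log2 fold change -0.67 ± 0.11, edgeR adjusted p = 0.00338), and Tead2 and the serpin gene Serpini2 fell by 0.55 and 0.49 on the log2 scale. These 3 falls were not past the threshold with library totals alone. Serpini2 also did not pass whichever library was left out (log2 fold changes -0.59, -0.38, -0.48 and -0.47 without A, B, C and D). Tead2 did not pass without B, C or D (-0.42, -0.61 and -0.47), nor Aqp12 without B or C (-0.60 and -0.63). Foxa3, a forkhead factor of endodermal organs, rose from 14.8 ± 0.425 to 31.0 ± 2.08 CPM (log2 fold change 1.06 ± 0.14, adjusted p = 0.000561). Adjusted over the list alone, 9 fell and 2 rose. The list did not pass without library B or D (adjusted p = 0.139 and 0.0598) or under the 10 CPM filter (adjusted p = 0.0648). Without library A, B, C or D, 2, 0, 0 or 1 of its members fell.

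Immediate-early genes, the first to be transcribed after a stimulus, were higher with the Paf1 guide as a list. Of 19 tested, 6 rose, none fell and 13 did not pass, with a median log2 fold change of 1.17 (camera adjusted p = 1.38e-19; adjusted p = 0.302 with an estimated correlation). Btg2 rose from 28.5 ± 2.04 to 85.8 ± 5.35 CPM (SD, n = 2; 3-fold, edgeR adjusted p = 1.36e-06), Jun from 7.65 ± 1.94 to 23.4 ± 2.49 CPM and Ier2 from 9.24 ± 1.21 to 20.9 ± 5.32 CPM. Egr1 and Fos, chosen after their values were seen, had wide spread within the Paf1 guide group and did not pass. Egr1 was at 3.44 and 2.93 CPM in the controls and at 198 and 72.0 CPM in libraries C and D. Ier2 did not pass without library A, B or C (log2 fold changes 1.30, 1.04 and 0.91). The list's median was 1.30, 1.04, 0.91 or 1.30 without library A, B, C or D. Adjusted over the list alone, 11 rose. The number of members that rose was 10 with library totals alone and 2, 2, 3 or 6 without library A, B, C or D.

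Heat-shock genes were also higher as a list, with 1 of 14 past the threshold and a median log2 fold change of 0.99 (camera adjusted p = 4.89e-08; adjusted p = 0.859 with an estimated correlation). The cytosolic chaperone gene Hsp90ab1 rose from 207 ± 18.3 to 370 ± 52.6 CPM (SD, n = 2; log2 fold change 0.84 ± 0.12, edgeR adjusted p = 0.00129). Hspd1, Chordc1 and Hsp90aa1 had log2 fold changes of 0.54, 0.60 and 1.29 and did not pass, although 4 members did when adjusted over the list alone. Library C stood apart in the inducible members. Hspa1b, chosen after its values were seen, was at 78.7 CPM there and at 4.42 CPM in library D, against 1.66 and 1.78 CPM in the controls. With library totals alone 6 members rose, and without library A, B, C or D, 1, 0, 3 or 7. The list's median was 0.53 without library C.

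Genes that respond to RAS-MAPK signaling and p53 targets were higher as lists. Of 17 tested RAS-MAPK genes, 2 rose, Etv5 and Myc, and 15 did not pass, with a median log2 fold change of 0.62 (camera adjusted p = 4.41e-07; adjusted p = 0.302 with an estimated correlation). Myc went from 19.8 ± 1.87 to 31.5 ± 6.12 CPM (SD, n = 2; log2 fold change 0.65 ± 0.15) and did not pass without library A, B or C (adjusted p = 0.276, 0.196 and 0.348), with DESeq2's Wald test or with limma-voom (adjusted p = 0.111 and 0.128), and Phlda1 and Spred2 had log2 fold changes of 2.09 and 0.67 without passing. Kras itself, chosen after its values were seen, was at 8.86 ± 1.41 and 9.54 ± 3.01 CPM and did not pass. Of 24 tested p53 targets, 4 rose and 20 did not pass, with a median log2 fold change of 0.23 (camera adjusted p = 0.000231; adjusted p = 0.425 with an estimated correlation). The 4 were the antiproliferative gene Btg2, which the immediate-early list also holds, the cell cycle inhibitor gene Cdkn1a (20.4 ± 0.00501 to 39.5 ± 3.39 CPM, log2 fold change 0.95 ± 0.13), Trp53inp1 (0.83) and Ccng1 (0.52). Ccng1 did not pass whichever library was left out (log2 fold changes 0.46, 0.58, 0.59 and 0.47 without A, B, C and D), nor did Trp53inp1 without A or D (0.66 and 0.65). The p53 target Mdm2, chosen after its values were seen, was at 14.8 ± 3.91 and 16.2 ± 0.176 CPM and did not pass. Adjusted over the list alone, 3 RAS-MAPK genes and 4 p53 targets rose. The numbers were 6 and 7 with library totals alone. Without library A, B, C or D, 1, 1, 1 or 2 RAS-MAPK genes and 2, 3, 3 or 2 p53 targets rose.

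Genes of pancreatic injury and metaplasia were higher as a list. Of 16 tested, 4 rose, 1 fell and 11 did not pass, with a median log2 fold change of 0.23 (camera adjusted p = 0.0135; adjusted p = 0.608 with an estimated correlation). Clusterin, Clu, rose from 605 ± 27.4 to 1107 ± 43.8 CPM (SD, n = 2; log2 fold change 0.87 ± 0.10, edgeR adjusted p = 0.000241). The simple-epithelium keratin genes Krt8 and Krt18 rose with log2 fold changes of 0.82 and 0.72 and the secreted lectin gene Reg3d with 0.65, while the trefoil peptide gene Tff2, named as the single member that fell, went from 816 ± 24.3 to 580 ± 38.9 CPM. Reg3d did not pass without library A, B or C (log2 fold changes 0.61, 0.70 and 0.46), nor Krt8 without B (0.74) or Krt18 without A (0.64). Adjusted over the list alone, 5 rose and 2 fell. The list did not pass without library B or D (adjusted p = 0.302 and 0.0582), when its median was 0.16 or 0.12. The median was 0.46 without library A and 0.36 without library C. Without A, B, C or D, 2, 2, 4 or 5 members rose. The fall of Tff2 did not pass whichever library was left out or with library totals alone, when 5 members rose and none fell. The duct list, of 19 tested, had no member past the threshold (camera adjusted p = 0.625), although 3 rose with library totals alone and 1 fell with a term for the split of libraries A and D against B and C, chosen after seeing the data. The duct keratin gene Krt19 was at 14.6 ± 0.114 and 18.9 ± 0.799 CPM.

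**Figure D3:**
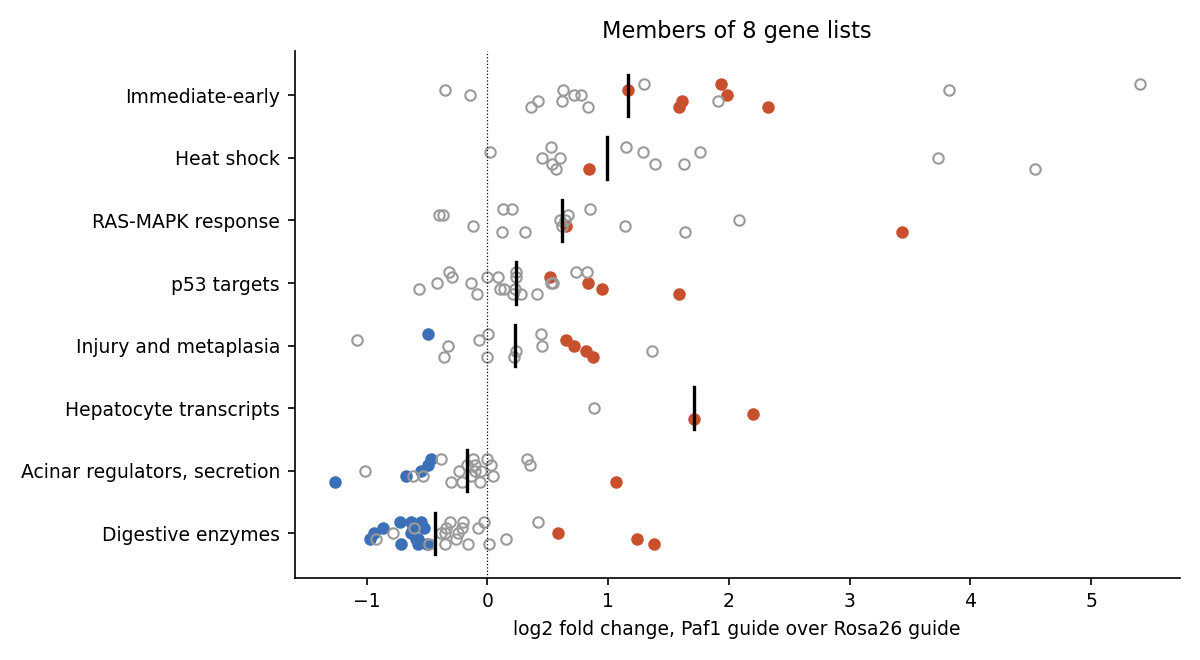
Log2 fold change (x axis, Paf1 guide over Rosa26 guide) of each tested member of 8 gene lists, with filled points past adjusted p 0.05, blue lower and red higher, open points for the rest and black lines for list medians. Medians run from -0.43 for digestive enzymes to 1.71 for the 3 hepatocyte transcripts, and most members of each list are open points, except in the hepatocyte list, where 2 of 3 are filled.

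Markers of other cell types gave a small number of changes. The hepatocyte list had 3 of its 16 members tested, of which Ttr and Alb rose and Trf did not pass (camera adjusted p = 5.09e-11; adjusted p = 0.302 with an estimated correlation). Ttr, which pancreatic islets also express, went from 16.0 ± 1.1 to 52.4 ± 3.18 CPM (SD, n = 2) and Alb from 0.768 ± 0.247 to 3.64 ± 0.642 CPM. Alb did not pass whichever library was left out (adjusted p = 0.110 to 0.239) or with limma-voom (adjusted p = 0.114), and DESeq2 gave it no adjusted p, so that 1 member of the list rose under these settings. Among 20 macrophage and dendritic cell genes Cd163 rose (log2 fold change 1.03 ± 0.24, edgeR adjusted p = 0.0377), and among 22 stellate and fibroblast genes Pdgfra rose (0.74 ± 0.17, adjusted p = 0.0316). Neither Cd163 nor Pdgfra passed whichever library was left out (adjusted p = 0.0607 to 0.427 and 0.118 to 0.227) or with limma-voom (adjusted p = 0.0992 and 0.0727). Pdgfra did not pass with DESeq2's Wald test (adjusted p = 0.140), which gave Cd163 no adjusted p. The number of stellate genes that rose was 5 with library totals alone. Neither list passed (camera adjusted p = 0.0635 and 0.099), but both did without a filter (adjusted p = 0.0413 and 0.0291) and with limma-voom (adjusted p = 0.00875 and 0.0265), the macrophage list with a term for the split of libraries A and D against B and C, chosen after seeing the data (adjusted p = 0.0091), and the stellate list under the 10 CPM filter (adjusted p = 0.0408). The medians depended on the library left out. That of the macrophage list was 0.91, -0.11, 0.56 or -0.03 without library A, B, C or D (adjusted p = 3.81e-09, 0.442, 0.00233 and 0.841), and that of the stellate list 0.36, 0.05, 0.31 or 0.08 (adjusted p = 0.0011, 0.886, 0.0776 and 0.207). No member passed in the lists for islet endocrine cells, endothelium, smooth muscle and pericytes, adipocytes, mesothelium, erythroid cells, T and NK cells or intestinal epithelium, whose camera adjusted p were 0.577, 0.625, 0.858, 0.74, 0.373, 0.882, 0.44 and 0.74. The T and NK cell list passed without a filter (median -0.62, adjusted p = 0.0078). The mesothelium list passed without library A or D (medians 1.07 and 0.47, adjusted p = 0.0393 and 0.0354) and had medians of -0.003 and 0.03 without B and C. The islet list passed without library B (median -0.24, adjusted p = 0.0368) and had medians of -0.01, -0.16 and 0.065 without A, C and D. Glucagon (Gcg) was at 80.5 ± 26.5 and 53.2 ± 2.02 CPM without passing.

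Immunoglobulin transcripts differed within both guide groups. Ighg2c, the constant region of IgG2c, chosen after its values were seen, had 3388 and 6 counts in control libraries A and B and 8 and 3193 in Paf1 guide libraries C and D. All immunoglobulin genes summed to 2264 and 15.5 CPM in the controls and to 281 and 1106 CPM with the Paf1 guide. The IgM constant region Ighm was highest in library C, at 115 CPM, against 14.5, 2.93 and 6.36 CPM in A, B and D. The 4 MHC class II genes examined summed to 294 and 86.3 CPM in the controls and to 103 and 227 CPM with the Paf1 guide. The B and plasma cell list and the antigen presentation list did not pass between the guides, with no member past the threshold (camera adjusted p = 0.553 and 0.831). The B and plasma cell list had a negative median and mean log2 fold change, -0.63 and -0.16, and the direction camera gave was up. Its median was 6.75, -1.64, 0.04 or -1.86 without library A, B, C or D, and it passed without A (adjusted p = 4.21e-05, against 0.153, 0.332 and 0.841). Without library A the antigen presentation list turned from a median of -0.13 to 0.79 (adjusted p = 0.000578), without library B it was -0.69 (adjusted p = 0.000173), without library C 0.32 (adjusted p = 0.185) and without library D -0.81 (adjusted p = 0.0243).

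**Figure D4:**
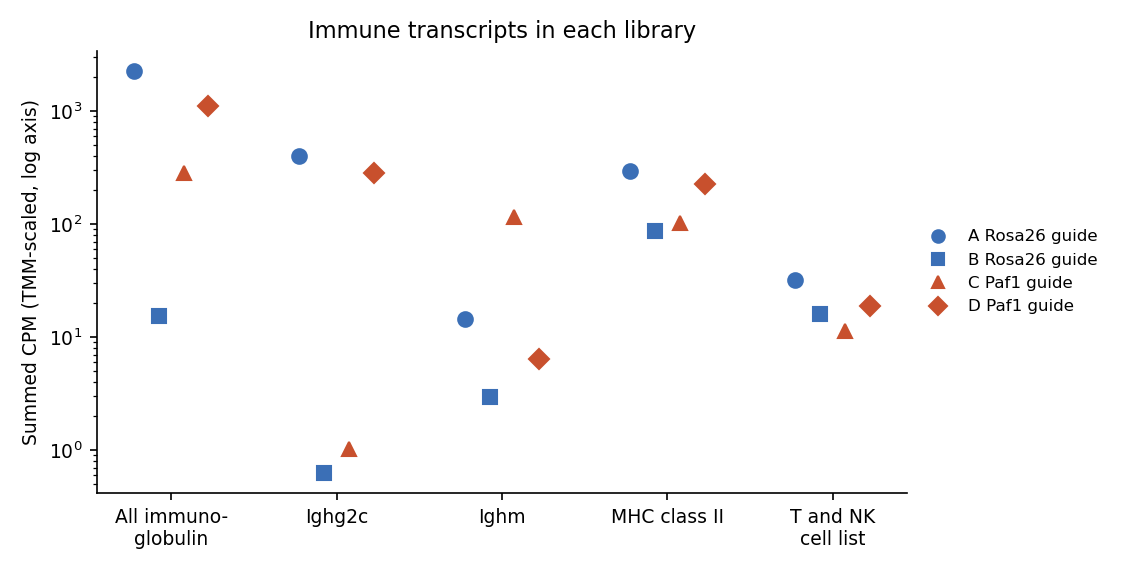
Summed CPM (y axis, TMM-scaled, log axis) of all immunoglobulin genes, Ighg2c, Ighm, 4 MHC class II genes and 23 T and NK cell genes in each library, with 1 point per library. Libraries A and D, which have different guides, are highest for Ighg2c (402 and 282 CPM) and MHC class II (294 and 227 CPM), and library C is highest for Ighm.

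Among lists tied to the function of the target, R-loop factors (26 tested) had Ddx5, an RNA helicase gene, as the member that rose (164 ± 2.61 to 260 ± 7.93 CPM, SD, n = 2; log2 fold change 0.67 ± 0.10, edgeR adjusted p = 0.00252), and the list did not pass (median 0.19, camera adjusted p = 0.0836). The number of its members that rose was 11 with library totals alone and 0 without library A or B. Its adjusted p was under the threshold with library totals alone, without a filter, under the 10 CPM filter, with DESeq2 and with limma-voom (0.0266, 0.0232, 0.0151, 0.0327 and 0.024). It was not under the threshold with any library left out. The list's median was 0.05, 0.23, 0.17 or 0.23 without library A, B, C or D. Elongation factors, the exosome and Integrator, DNA repair and the PAF1 complex had no member past the threshold (camera adjusted p = 0.74, 0.868, 0.706 and 0.882). Across tested genes with a single position, log2 fold change and gene span had a Spearman's rho of -0.0609, and the quintile of longest genes (spans of 68121 bases or more) had a median of -0.06, with 14 rises and 41 falls. Genes are not independent replicates, and rho was -0.0908, -0.0324, -0.0564 or -0.049 without library A, B, C or D, -0.0342 without a filter and -0.092 under the 10 CPM filter.

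The remaining lists did not pass. The chaperone gene Hspa5 rose in the unfolded protein response list (log2 fold change 0.59 ± 0.12, edgeR adjusted p = 0.0151; not past the threshold without library A, B or C), and Atf5 in the integrated stress response list and Cxcl12 in the inflammatory mediator list, both named as single changed members, fell by 0.95 and 0.77. These lists had camera adjusted p of 0.706, 0.264 and 0.862. The interferon list (29 tested, median -0.28, adjusted p = 0.0574) had no member past the threshold, and its median was 0.13, -0.61, -0.11 or -0.56 without library A, B, C or D (adjusted p = 0.502, 7.93e-08, 0.625 and 0.00103). It passed without a filter (adjusted p = 0.0374) and with the term for the split of the libraries (adjusted p = 0.0189). Proliferation, circadian clock, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal protein and replication-dependent histone genes had no member past the threshold (camera adjusted p = 0.263, 0.275, 0.275, 0.201, 0.542 and 0.72). Without library A the proliferation, clock and histone lists passed (medians 0.68, 0.26 and 0.64, adjusted p = 0.000578, 0.0492 and 0.00261). Their medians were -0.09, -0.0002 and -0.26 without library B and -0.09, 0.01 and -0.21 without library D, and none of the 3 passed without B, C or D. The mitochondrially encoded list passed without library C (median -0.56, adjusted p = 0.000434) and had a median of 0.03 without D, and it passed with limma-voom (adjusted p = 0.0268), as did the oxidative phosphorylation list without a filter (adjusted p = 0.0419). With library totals alone the interferon, oxidative phosphorylation and ribosomal protein lists passed (adjusted p = 0.000822, 0.00217 and 0.0262). No list passed fry's test of movement in one direction (smallest adjusted p = 0.0941), and 8 passed its test of change in either direction. These were the sex-linked, hepatocyte, RAS-MAPK, p53, injury and acinar regulator lists, and the oxidative phosphorylation and duct lists, which did not pass camera. The immediate-early, heat-shock and digestive enzyme lists did not pass fry's test of change in either direction (adjusted p = 0.0905, 0.255 and 0.0809).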

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

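The term for the split of the libraries and the settings without X and Y genes or without immunoglobulin genes were chosen after seeing the data. The 289 changed genes (142 higher, 147 lower) became 291, 291, 264, 301, 280 and 313 with DESeq2's size factors, with upper-quartile factors and without the 50 dominant, the mitochondrial, the X and Y or the immunoglobulin genes, and 350 under the 10 CPM filter. With library totals alone 1600 genes passed (1560 higher, 40 lower), and 181 of the 289 remained, all in the same direction. Without a filter 545 passed (303 higher, 242 lower) among 28380 tested. DESeq2's Wald test called 148 (74 higher, 74 lower), 136 of them shared, with 7868 adjusted p not given, and limma-voom 162 (88 higher, 74 lower), 154 of them shared. With the term for the split, 583 passed (272 higher, 311 lower), including the 289. The term follows the largest axis of variation in these same libraries, so the higher count is no separate support for the 289. Leaving out a library gave 71 to 129 genes, 50 to 96 higher and 21 to 59 lower, with the lone library of a group assumed to vary like the pair. Of the 107 further genes followed by name, many had no call in the main fit. Among those called, calls were lost whichever library was left out, most often without B, and none changed sign while called. The 9 lists past the threshold became 15 without a filter and 8 to 13 under the other settings with all libraries; the range without a library was 9 to 17, the highest without A. The enzyme list turned without the 50 dominant genes (median -0.28, adjusted p = 0.783), where 6 enzymes remained tested, and the antigen presentation list without library A (median 0.79, adjusted p = 0.000578), with medians down to -0.81 (without D) when other libraries were left out. The sex-linked list did not pass with DESeq2's Wald test (median 9.13, adjusted p = 0.333). The rho of gene span was -0.092 under the 10 CPM filter, -0.0342 without a filter and -0.0908 to -0.0324 without a library; the cause was not tested. Paf1 did not pass under any setting that tested it (-0.65 to -0.11), and under the 10 CPM filter it was not tested. No paired analysis was possible because the columns carry no replicate number. The simulation had 2 libraries per group at the measured depth, with genes drawn independently at the trended spread of the fit. It recovered 7.46% of genes changed 1.5-fold, and the part of depth in this was not tested.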

Other observations

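Tests of the sex chromosomes, of sex on autosomal genes, of the Paf1 transcript, of other splits, of scaling, of the spread among enzymes and of the guide or sex behind the immunoglobulin counts were chosen after the results were seen, and the tests of near-identical copies and of T cell transcripts before.

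The genes in this paragraph were chosen after their values were seen and were not tested as groups. The nuclear RNAs Malat1 and Neat1 went from 2996 ± 232 to 5767 ± 399 CPM and from 231 ± 41.9 to 551 ± 31.6 CPM (SD, n = 2; log2 fold changes 0.94 ± 0.11 and 1.25 ± 0.12, edgeR adjusted p = 0.000247 and 5.67e-05). The snoRNA host genes Gas5 and Taf1d rose with log2 fold changes of 0.89 and 0.93, and the nucleolar protein genes Npm1, Nop56 and Ncl with 0.71, 0.80 and 0.48. Selenop, the plasma selenium carrier, rose 3.34-fold (374 ± 14.9 to 1249 ± 103 CPM), and the retinoic acid enzyme gene Aldh1a1 and the nuclear receptor gene Hnf4a rose with 1.19 and 0.92. The lipogenic regulator gene Srebf1, the diacylglycerol lipase gene Dagla and the gamma-glutamyl transferase gene Ggt1 fell by 0.93, 1.02 and 0.75 on the log2 scale. All of these changes also follow the sex of the animals.

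The 289 changed genes cannot be assigned to the guide from these libraries. Dosage of X and Y genes is argued against as the main source, since 279 of the changed genes lie on autosomes. The sex of the animals acting on autosomal genes cannot be told apart from the guide, because the number of libraries in which sex and guide are crossed is 0. Loss of the Paf1 transcript also stays open, since its log2 fold change of -0.46 did not pass the threshold and a cut that leaves transcript in place is not excluded. The absence of a cut is not excluded either. The 4 libraries allow 3 splits, of which 1, the real one, gave 289 genes and the highest other gave 30, and 3 splits are too few for a share under 0.05. The largest axis of variation, the first principal component of log2 CPM (41.6% of the variance), set libraries A and D apart from B and C. The guide groups lay apart on the second component (39.1%).

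For the lower digestive enzymes, how far scaling sets the size of the fall stays open. A comparison with other genes, planned before, cannot test it, since a factor per library moves all genes alike. The enzymes' median went from -0.43 to -0.0802 with library totals alone, but they held 64.2% to 70.1% of all counts, so totals alone keep their sum nearly fixed. Reads moved between near-identical copies are argued against by the 10 of 14 fallen enzymes that lie outside the amylase, trypsin and Cela3 families. If only acinar cells make these enzymes, and all alike, a lower share of acinar cells alone would lower them by the same factor. The log2 fold changes of the 22 enzymes outside the families ran from -0.97 to 0.42 around a median SE of 0.11. Their chi-square per degree of freedom was 7.2, with the standard errors taken as known and the genes as independent. Under these assumptions the spread counts against a lower acinar share alone and does not exclude it as a part of the fall. Beside scaling, a further candidate explanation is a change within acinar cells. It may come from the guide or from the sex of the animals, 2 causes this design does not separate.

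Immunoglobulin and MHC class II genes were high in libraries A and D, which carry different guides and different sexes. Fitted against libraries B and C, this split gave 30 higher genes, 19 of them immunoglobulin genes, and the third split gave 0 (edgeR; 503 and 178 genes at an unadjusted p under 0.05). Ighg2c, chosen after its values were seen, differed within both guides, by 276-fold in the smaller of the ratios. Guide and sex alone cannot produce a difference within a guide. This follows from how the split was defined and is not a separate test. Ighm was highest in library C and did not follow the split. A lymph node in the dissected piece stays open, since T cell transcripts were 1.86-fold higher in these libraries, with library pairs between 1.18-fold and 2.81-fold. B cell genes other than immunoglobulins, summed, were 1.27-fold higher, with pairs between 1.07-fold and 1.54-fold. The plasma cell genes Jchain and Mzb1, summed, were 9.68-fold higher, with 3.25-fold in the smallest pair. No rule was fixed for these sets. No label names a housing group, an age or an infection status, and these were not tested.

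The transcript CT010467.1, chosen after its values were seen, differed within the Paf1 guide group, with 93160 and 16566 counts in libraries C and D (12969 and 1704 CPM of the library total). Control libraries A and B had 57181 and 69881 counts (6277 and 6156 CPM of the library total). The cause was not tested.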
